A study of Homo sapiens with 30 samples.

How the data were processed

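Gene expression was measured on 30 Affymetrix Human Genome U133 Plus 2.0 arrays, which carry 54675 probe sets. Lymphocytes had been sorted from human blood mononuclear cells by flow cytometry, per the labels, with antibodies to CD3, CD56, CD14, 3 inhibitory killer cell immunoglobulin-like receptors (KIR2DL1, KIR2DL2/3 and KIR3DL1) and the Valpha24 T cell receptor chain. The 6 groups of 5 arrays were CD56- T cells, NK cells, CD56+ T cells, KIR- and KIR+ fractions of CD56+ T cells, and invariant NKT (iNKT) cells. Per the labels, purity exceeded 98% in the first 5 groups, and in iNKT cells it exceeded 95% by Valpha24 and 90% by CD1d tetramer. The RNA, 10 to 100 ng, was amplified in 2 cycles before labelling, per the labels.

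The deposited values are signal intensities on a linear scale, 1 per probe set and array. The submitters' processing notes name MAS5, GCOS 1.4 and Partek 6.4, without their roles. The values themselves showed that each array had been scaled to a common level: the mean after trimming 2% of the values at each end was 499.8 to 499.9 on every array, and medians ran from 56.0 to 107.6. No further normalization was applied. All columns belonged to a sample.

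Probe sets were named through the platform annotation, in which 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none. Symbols were checked against the gene table of GRCh38.p14, which changed 0 of them, and no coordinates were used. Left out were 62 control probe sets, 59 probe sets of Y-linked genes and of transcripts of X inactivation, and probe sets with no symbol or several. A probe set entered if its signal was above its array's median on at least 5 arrays, which 35143 did, 27594 of them with 1 symbol. Each gene was represented by the probe set with the highest mean over the 30 arrays, giving 14327 genes. Probe sets of the _x_at and _s_at types can bind related transcripts, and values of KIR genes, which are close paralogs, are uncertain for that reason.

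Differences were tested with limma 3.58.1 in R 4.3.3 (linear model on 6 group means, empirical Bayes with a trend, 24 residual degrees of freedom) on log2(signal + 16), with all 30 arrays in 1 fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and the number changed at least 2-fold is given beside it. All adjusted p-values of genes come from this model unless another is named. Fold changes are on the log2(signal + 16) scale, which understates differences of dim genes. Many are given with a standard error (SE, log2 scale) or a 95% interval. Where the lower group lay below its array median on all its arrays, its level is only a bound. The same was done where only its mean lay below, a rule added after the data were seen, with the number of its arrays above the median given. The fold is then written as at least the ratio to the dimmer group, taken on each array at the higher of its value and the array median. The number of arrays limits the precision of all values. Donors are not stated in the labels, so p-values measure the spread between these samples, which may be partly technical.

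The design, the 23 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Genes were named by 3 parts of a rule: the 8 largest called changes in each direction among genes whose groups did not overlap, up to 4 called members of each list with the largest fold, and the genes of the sort with ZBTB16, TBX21 and EOMES. The lists (measured genes) were T lineage (17), naive and central memory (16), KIR family (13), NK receptors and adaptors (17), cytotoxic effectors (16), lymphocyte transcription factors (24), cytokines and chemokines (18), chemokine and homing receptors (25), cytokine receptors (24), innate-like T cell genes (17), antigen receptor signalling (17), inhibitory receptors (15), gamma delta T cell receptor (2), regulatory T cell markers (8), markers of B cells (13), monocytes (17), platelets (11), erythroid cells (5), dendritic cells (8) and granulocytes (7), proliferation (20), immediate early and heat shock (20), and interferon-stimulated (19). Lists were tested with camera at a preset correlation of 0.01 and adjusted over 161 tests (23 lists in 7 comparisons), then with an estimated correlation and with fry. Counts of called members are given over all genes and adjusted over the list alone.

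A position between CD56- T cells (0) and NK cells (1) was computed for each array as the median over the genes called and at least 2-fold different between those groups, in a fit without arrays of its own replicate number (1426 to 2231 genes). Position differences and the correlation across genes of the KIR+ minus KIR- difference with 2 lineage differences were tested by two-sided exact permutation of arrays. The labels number the arrays 1 to 5 in each group. Deviations from the group means correlated between arrays of the same number in all 10 pairs of groups without iNKT cells (0.104 to 0.562, against a mean of -0.0839 for other numbers), but not in the 5 pairs with iNKT cells (-0.153 to 0.140). The numbers were therefore taken to pair the 25 arrays without iNKT cells, and a fit of those arrays with the replicate number as a block is given beside a result where it changed the call or moved a count by more than 1.5 times. No arrays held identical values, and the highest correlation between any 2 arrays was 0.970.

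The ratio of 3 prime to 5 prime control probe sets of ACTB and GAPDH, a measure of how far amplified RNA is shortened, was computed per array as a mean log2 value. Alternatives were other filters, pseudocounts of 1 and 64, quantile normalization, median centring, array weights, no trend, other choices of probe set, only the arrays of the groups compared, the replicate block, and each array left out in turn. Where leaving out 1 array moved the fold of a called gene by more than 1.5 times, the log2 difference is given before and after, except for KIR and HLA genes. Chosen after the data were seen were the 25-array block, the ratio as a covariate and the list tests under both.

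The scripts were tested on simulated data with the 14327 genes of KIR+ minus KIR-, 50 changed per size. Without a block, 22% of 2-fold, 72% of 4-fold and 100% of 8-fold changes were recovered, and 7 unchanged genes were called. With simulated shared donors, the block recovered 28%, 96% and 98% and called 8 unchanged genes. Camera called 10 of 10 shifted and 0 of 90 other lists of independent simulated genes, so false calls of correlated lists were not tested. Groups placed at 0.25, 0.5 and 0.75 between the lineages were recovered at 0.289, 0.500 and 0.704. Figures used matplotlib 3.10.9 in Python 3.11.15.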

Results

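Transcript levels were compared between the 6 sorted lymphocyte populations (5 arrays each). CD56 and the KIRs are surface molecules best known from NK cells, and iNKT cells are T cells with an invariant receptor for lipids presented by CD1d. CD3D, a chain of the T cell receptor complex, had a geometric mean signal of 27621 in CD56- T cells, 15565 in CD56+ T cells and 558 in NK cells. The CD56 gene NCAM1 had a mean signal of 84.5 in CD56- T cells, 1548 in CD56+ T cells, 543 in iNKT cells and 4414 in NK cells. The first principal component, with 29.99% of the variance of the 14327 genes tested, separated all 5 iNKT arrays from the other 25. The 3 prime to 5 prime ratio of the control transcripts ranged over the arrays from 3.25 to 129 for ACTB and from 1.60 to 63.3 for GAPDH.

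Of 15 pairs of groups, iNKT cells against the KIR+ fraction had most calls (5853). Fewest were in KIR- against unfractionated CD56+ T cells: limma called 0, and 164 genes had an unadjusted p under 0.05. The KIR+ fraction differed from unfractionated CD56+ T cells in 8 genes, all lower. These counts are without the replicate block. KIR- and CD56+ T arrays pair, but no block count was made, so 0 calls do not show likeness.

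**Figure D1:**
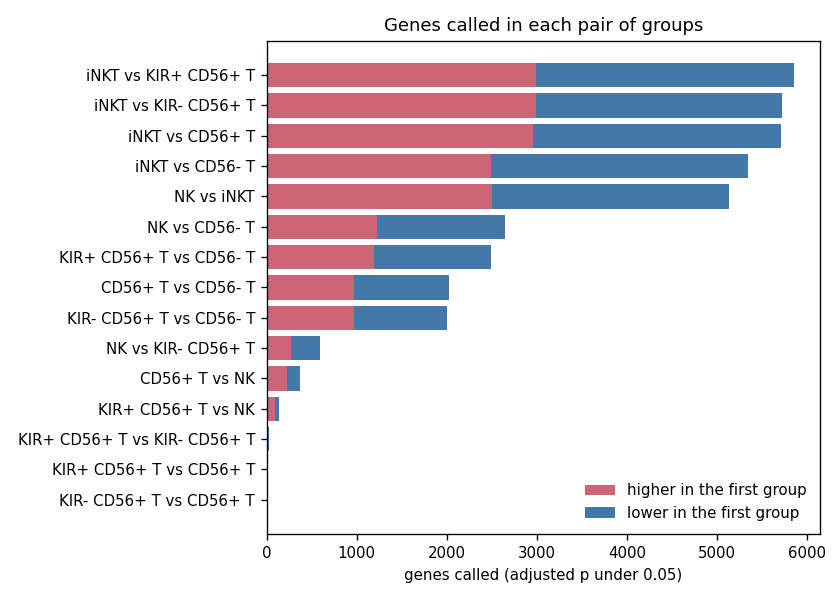
Genes called higher and lower in each of the 15 pairs of groups (x axis, number of genes at an adjusted p under 0.05; stacked bars for the 2 directions). Pairs with iNKT cells have at least 5133 genes, and the 3 pairs within CD56+ T cells have at most 25.

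NK cells and CD56- T cells are the 2 reference lineages of the series (n = 5 each). SH2D1B, an adaptor of SLAM family receptors, was at least 137-fold (adjusted p = 4.83e-09) higher in NK cells, and NCAM1 was at least 34.5-fold (adjusted p = 1.74e-12) higher. Genes of the T cell receptor and its costimulation were lower in NK cells: CD3D by 48.2-fold (95% interval 29.1 to 79.8), the costimulatory receptor CD28 by at least 75.8-fold (adjusted p = 1.21e-09) and CD5, an inhibitory coreceptor of T cells, by 68.7-fold (95% interval 37.3 to 127). All 13 measured KIR genes were higher, KIR3DL3 by at least 42.1-fold (adjusted p = 1.53e-06) and KIR2DL1 by at least 24.7-fold (adjusted p = 1.30e-06), on probe sets that can bind several members of the family.

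Among the other largest differences, IGFBP7 was 137-fold (log2 7.09, SE 0.89) higher in NK cells, LINGO2 at least 20.8-fold (adjusted p = 4.67e-12) and MGAM at least 20.1-fold (adjusted p = 1.59e-07). TTC38 was 59.9-fold (log2 5.90, SE 0.61) higher, although 1 of its 2 other probe sets pointed the other way. Lower in NK cells were MAL 222-fold (log2 -7.79, SE 0.73), ADTRP at least 34.4-fold (adjusted p = 1.75e-11), UBASH3A at least 30.1-fold (adjusted p = 6.53e-13), THEMIS at least 27.5-fold (adjusted p = 1.21e-09), RCAN3 68.8-fold (log2 -6.10, SE 0.70) and FBXL16 at least 33.8-fold (adjusted p = 4.80e-10). THEMIS and UBASH3A act in T cell receptor signalling. Among genes given with lower bounds, the lower group lay above its array median on 1 of 5 arrays for SH2D1B, CD28 and THEMIS, on 3 for NCAM1 and on some for KIR3DL3 and KIR2DL1.

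The T lineage list was lower in 17 of 17 measured genes, both over all genes and adjusted over the list alone (camera adjusted p = 3.38e-30, and adjusted p = 2.16e-05 with an estimated correlation). Of the naive and central memory genes, 15 of 16 were lower over all genes and 16 adjusted over the list alone (adjusted p = 2.39e-20, and 0.0292 with an estimated correlation). They included the homing receptor CCR7 37.1-fold, the transcription factor LEF1 27.3-fold and the survival cytokine receptor IL7R 24.5-fold. All 13 KIR genes were called on either count (adjusted p = 5.23e-18, but adjusted p = 0.0680 with an estimated correlation). NK receptors and adaptors had 10 of 17 higher over all genes, and 11 higher and 1 lower adjusted over the list alone (adjusted p = 8.62e-11, and 0.0135 with an estimated correlation), with KLRF1 30.9-fold and CD160 15.6-fold higher. Cytotoxic effectors had 11 of 16 higher and 1 lower on both counts (adjusted p = 4.22e-08, but adjusted p = 0.131 with an estimated correlation). The protease gene GZMB was 19.996-fold (95% interval 9.05 to 44.2) higher and the pore-forming PRF1 8.86-fold (95% interval 4.79 to 16.4).

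Transcription factors had 8 of 24 higher and 4 lower over all genes, 10 and 6 adjusted over the list alone, and 13 and 6 with the replicate block (adjusted p = 0.0336, but adjusted p = 0.273 with an estimated correlation). The promyelocytic zinc finger gene ZBTB16 was 9.06-fold (log2 3.18, SE 0.74) higher, TBX21 5.03-fold (log2 2.33, SE 0.40) and EOMES 4.80-fold (log2 2.26, SE 0.37), the last 2 being T-box factors of effector lymphocytes. Chemokine and homing receptors went both ways, 6 of 25 higher and 10 lower on both counts, among them ITGAX at least 26.7-fold and CX3CR1 16.8-fold higher. Cytokine receptors had 8 of 24 higher and 6 lower over all genes, and 8 and 7 adjusted over the list alone (median 0.004 and test on the higher side, mean -0.04), with IL18RAP 21.1-fold and IL2RB 7.08-fold higher. Antigen receptor signalling genes had 6 of 17 higher and 2 lower over all genes, and 8 and 4 adjusted over the list alone, with the kinase SYK 17.7-fold higher (adjusted p = 0.000956, but adjusted p = 0.0933 with an estimated correlation). LAT2 was 25.5-fold higher, although its other probe set pointed the other way. Of the marker lists of other blood cells, limma called 0 of 17 monocyte, 0 of 11 platelet and 0 of 5 erythroid genes, with 3, 0 and 1 at an unadjusted p under 0.05. For monocyte markers the median log2 difference was -0.18, while the mean (0.04) and the test were on the higher side. The replicate block called 2 monocyte genes higher and 1 lower, and 1 platelet gene lower. CD14, stained in the sort, did not pass the test (log2 difference -0.19, SE 0.87, adjusted p = 0.911). Interferon-stimulated genes had 1 of 19 higher and 1 lower over all genes, 1 higher adjusted over the list alone, and 5 higher and 5 lower with the replicate block. Dendritic cell markers had 5 of 8 higher and 1 lower over all genes, and 6 and 1 adjusted over the list alone (adjusted p = 0.000931, but adjusted p = 0.133 with an estimated correlation). PTGDS was 13.7-fold higher, and GZMB is a member of that list too.

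limma called 2652 genes, 1228 higher and 1424 lower in NK cells, 2179 of them at least 2-fold, and 4575 (2148 higher, 2427 lower) with the replicate block. In all 5 pairs the 3 prime to 5 prime ratio was higher in NK cells, by 1.10 on the log2 scale in the mean (two-sided exact permutation test, p = 0.151, and 0.0625 with paired sign changes, the smallest possible). The block with this ratio, chosen after the data were seen, gave 2829 calls (1309 higher, 1520 lower). Against the block alone, calls went from 13 to 12 for cytotoxic effectors (median log2 difference 1.91, median SE 0.28, to 1.39, SE 0.38), from 12 to 11 for antigen receptor signalling (0.63, SE 0.22, to 0.21, SE 0.28) and from 10 to 6 for interferon-stimulated genes (-0.16, SE 0.24, to 0.03, SE 0.33). They went from 13 to 10 for NK receptors (2.64, SE 0.38, to 2.67, SE 0.49) and from 3 to 1 for monocyte markers (-0.18, SE 0.50, to -0.10, SE 0.68). CD160 went from a log2 difference of 3.96 to 3.34, CX3CR1 from 4.07 to 3.35, GZMB from 4.32 to 3.54 and PRF1 from 3.15 to 2.50 without CD56- T replicate 1. TTC38 went from 5.90 to 6.59 without CD56- T replicate 2. CD160 went from 3.96 to 4.65 without CD56- T replicate 3.

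CD56+ T cells were compared with CD56- T cells (n = 5 each). NCAM1 was at least 12.2-fold (adjusted p = 3.48e-08) higher in CD56+ T cells. IL18RAP, a chain of the interleukin-18 receptor, was 17.4-fold (95% interval 8.50 to 35.7) higher, and the nucleic acid sensor ZBP1 at least 11.5-fold (adjusted p = 4.20e-05). CCR7, which guides T cells to lymph nodes, was 14.9-fold (95% interval 7.42 to 29.8) lower, and MAL was 22.5-fold (95% interval 8.10 to 62.6) lower. CD4 was 6.71-fold (95% interval 3.04 to 14.8) lower.

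Also higher were the kinase gene MAP3K8 15.96-fold (log2 4.00, SE 0.50), DLG5 14.6-fold (log2 3.87, SE 0.55), RAP1GAP2 14.6-fold (log2 3.86, SE 0.62) and NME8 at least 5.03-fold (adjusted p = 5.53e-05). Lower were NEFL at least 10.3-fold (adjusted p = 4.18e-06), ADTRP 17.1-fold (log2 -4.10, SE 0.49), DSC1 at least 7.21-fold (adjusted p = 0.000248), TCEA3 15.04-fold (log2 -3.91, SE 0.63), BEX3 14.02-fold (log2 -3.81, SE 0.80) and FHIT 13.4-fold (log2 -3.75, SE 0.52). CD3D (log2 difference -0.83, SE 0.36, adjusted p = 0.121), CD3E (log2 difference -1.51, SE 0.54, adjusted p = 0.0559) and CD3G (log2 difference -0.66, SE 0.39, adjusted p = 0.273) did not pass the test. The replicate block called CD3D (adjusted p = 0.0177) and CD3E (adjusted p = 0.000470) lower.

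Innate-like T cell genes were higher in 12 of 17 over all genes and in 14 adjusted over the list alone (camera adjusted p = 8.24e-12, but adjusted p = 0.0668 with an estimated correlation). The malic enzyme gene ME1 was 11.1-fold higher, the receptor kinase LTK at least 9.26-fold and COLQ at least 5.29-fold. Naive and central memory genes were lower in 10 of 16 over all genes and 13 adjusted over the list alone (adjusted p = 3.77e-11, but adjusted p = 0.0984 with an estimated correlation), with LEF1 8.73-fold lower. T lineage genes were lower in 6 of 17 over all genes, 13 adjusted over the list alone and 14 with the replicate block (adjusted p = 1.05e-05, but adjusted p = 0.0863 with an estimated correlation). CD27, a costimulatory receptor, was 7.72-fold lower and CD5 3.60-fold.

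Cytotoxic effectors had 9 of 16 higher over all genes, and 10 higher and 1 lower adjusted over the list alone (adjusted p = 2.05e-07, but adjusted p = 0.143 with an estimated correlation). GZMB was 9.76-fold (log2 3.29, SE 0.56) higher and GNLY, a lytic granule protein, 7.93-fold (log2 2.99, SE 0.46). NK receptors and adaptors were higher in 8 of 17 over all genes and 9 adjusted over the list alone (adjusted p = 1.67e-06, but adjusted p = 0.0668 with an estimated correlation), with KLRF1 8.83-fold and KLRD1 5.14-fold higher. SH2D1B was at least 5.72-fold higher on its brighter probe set, while the other pointed the other way. KIR genes were higher in 7 of 13 over all genes, 9 adjusted over the list alone and 12 with the replicate block (adjusted p = 1.88e-08, but adjusted p = 0.250 with an estimated correlation). KIR2DL1 was at least 3.45-fold higher and KIR3DL1 5.41-fold. KIR2DL3 (log2 difference 1.76, SE 0.62, adjusted p = 0.0547) was called only with the replicate block (adjusted p = 0.00114).

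Transcription factors had 10 of 24 higher and 2 lower over all genes, 13 and 5 adjusted over the list alone, and 14 and 6 with the replicate block (adjusted p = 0.000313, but adjusted p = 0.0668 with an estimated correlation). TBX21 was 3.82-fold higher, EOMES 3.89-fold and ZBTB16 5.18-fold. Without CD56+ T replicate 5, where ZBTB16 stood apart (8.74, against 12.55 or more on the other 4 arrays), its log2 difference went from 2.37 to 3.19. Cytokines and chemokines had 4 of 18 higher over all genes, 4 higher and 1 lower adjusted over the list alone, and 8 and 2 with the replicate block, led by TNFSF14 at least 5.07-fold higher (camera adjusted p = 0.0775, and 0.0168 with the replicate block). Cytokine receptors had 8 of 24 higher and 4 lower over all genes, 9 and 5 adjusted over the list alone, and 11 and 8 with the replicate block. Of the immediate early and heat shock genes, 4 of 20 were higher over all genes, 5 adjusted over the list alone, and 6 higher and 2 lower with the replicate block (camera adjusted p = 0.0520, and 0.0171 with the replicate block). NR4A2 and NR4A3, nuclear receptors induced by antigen receptor signals, were 3.83-fold and 4.05-fold higher. The 3 prime to 5 prime ratio was higher in CD56+ T cells in all 5 pairs, by 1.44 on the log2 scale in the mean. The two-sided exact permutation test gave p = 0.0556 (adjusted p = 0.194 over 7 tests), and paired sign changes 0.0625, the smallest possible.

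limma called 2029 genes, 1054 of them lower, and 1679 at least 2-fold. The replicate block raised this to 4438 (1962 higher, 2476 lower). With the ratio added to the block, chosen after the data were seen, it was 1782 (883 higher, 899 lower). Calls then went from 12 to 7 for KIR genes (median log2 difference 2.44, median SE 0.48, to 2.05, SE 0.75). They went from 14 to 6 for T lineage genes (-1.30, SE 0.36, to -1.06, SE 0.51). Cytotoxic effectors went from 11 to 6 (1.21, SE 0.28, to 0.80, SE 0.43), naive and central memory genes from 15 to 10 (-2.66, SE 0.41, to -2.26, SE 0.62) and cytokine receptors from 19 to 10 (0.31, SE 0.24, to 0.14, SE 0.37). Transcription factors went from 20 to 14 (1.08, SE 0.25, to 1.22, SE 0.37), cytokines from 10 to 4 (0.62, SE 0.41, to 0.43, SE 0.64), NK receptors from 9 to 7 (1.70, SE 0.38, to 1.39, SE 0.56) and innate-like genes from 13 to 11 (1.86, SE 0.41, to 2.54, SE 0.63). The SE was wider for all genes of these lists. For lower bounds, the lower of the 2 groups lay above its array median on 1 of 5 arrays for ZBP1, NEFL, DSC1, SH2D1B and TNFSF14, on 2 for LTK, on 3 for NCAM1 and on some for KIR2DL1. GZMB went from a log2 difference of 3.29 to 2.50 and ZBP1 from 4.96 to 5.60 without CD56- T replicate 1. MAL went from -4.49 to -5.11 without CD56+ T replicate 3. LTK went from 3.63 to 4.41 and ME1 from 3.47 to 4.20 without CD56+ T replicate 5. Calls ended without single arrays (their number of 10) for NR4A2 (7), NR4A3 (2) and ZBTB16 (6) (highest adjusted p = 0.109). CD3D (-1.09, adjusted p = 0.0273) and CD3E (-1.69, adjusted p = 0.0335) were called without CD56- T replicate 1.

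CD56+ T cells were compared with NK cells, which share CD56 (n = 5 each). CD3D was 27.2-fold (95% interval 16.4 to 44.97) higher in CD56+ T cells, CD8B, a chain of the CD8 coreceptor, 24.4-fold (95% interval 10.4 to 57.5), and CAMK4, a calcium-dependent kinase, 24.3-fold (95% interval 12.6 to 46.8). SH2D1B was 23.9-fold (95% interval 7.60 to 75.1) lower than in NK cells, IGFBP7 18.4-fold (95% interval 5.25 to 64.3) and the ectoenzyme CD38 13.4-fold (95% interval 4.99 to 35.8). NCAM1 was 2.83-fold (95% interval 1.69 to 4.75) lower.

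Further genes higher in CD56+ T cells were RBM24 at least 12.3-fold (adjusted p = 0.000834), ME1 at least 22.5-fold (adjusted p = 2.97e-05), the water channel AQP3 25.6-fold (log2 4.68, SE 0.75) and the receptor SLAMF1 at least 11.98-fold (adjusted p = 1.69e-06). CD28 was at least 21.6-fold (adjusted p = 3.07e-06) higher, with 1 of its 2 other probe sets pointing the other way. CHST2 was 14.6-fold (log2 -3.87, SE 0.63) lower, RBPMS2 at least 5.88-fold (adjusted p = 6.96e-05), LINGO2 11.9-fold (log2 -3.58, SE 0.42), DAB2 11.2-fold (log2 -3.49, SE 0.58) and ZMAT4 at least 5.08-fold (adjusted p = 4.84e-05).

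T lineage genes were higher in 14 of 17 over all genes and 16 adjusted over the list alone (camera adjusted p = 1.35e-49, and 4.03e-07 with an estimated correlation), with CD3G 10.6-fold and CD3E 5.30-fold. Innate-like T cell genes were higher in 5 of 17 over all genes, 8 adjusted over the list alone and 9 with the replicate block (adjusted p = 5.06e-08, but adjusted p = 0.131 with an estimated correlation). CCR6, the receptor of CCL20, was at least 7.87-fold higher and CCL20 itself at least 3.79-fold. Also higher were LTK at least 10.1-fold and the surface peptidase DPP4 9.80-fold. Naive and central memory genes were higher in 5 of 16 over all genes and in 10 both adjusted over the list alone and with the replicate block (adjusted p = 4.15e-13, but adjusted p = 0.0683 with an estimated correlation). IL7R was 13.7-fold higher, and LTB 11.3-fold on its brighter probe set, while its other pointed the other way.

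KIR genes were lower in 6 of 13 over all genes, and in 13 both adjusted over the list alone and with the replicate block (adjusted p = 5.37e-14, but adjusted p = 0.105 with an estimated correlation). KIR2DL1 was 7.14-fold lower, KIR2DL2 6.71-fold, KIR2DL3 5.13-fold and KIR3DL1 5.24-fold. NK receptors and adaptors were lower in 5 of 17 over all genes, 7 adjusted over the list alone and 9 with the replicate block (adjusted p = 2.18e-06, but adjusted p = 0.0668 with an estimated correlation), with the signalling chain FCER1G 5.32-fold lower. Antigen receptor signalling genes had 1 of 17 higher and 5 lower over all genes, and 1 and 7 adjusted over the list alone (adjusted p = 0.000749, but adjusted p = 0.0863 with an estimated correlation), with SYK 7.997-fold lower. Inhibitory receptors went both ways: 2 of 15 were higher and 3 lower over all genes, 4 and 5 adjusted over the list alone, and 4 and 6 with the replicate block (median log2 difference 0.002, but mean -0.05 and test on the lower side). CTLA4 was at least 5.54-fold higher and LAG3 at least 8.13-fold, and HAVCR2 was 7.68-fold lower. Proliferation genes were lower in 2 of 20 over all genes, 3 adjusted over the list alone and 5 with the replicate block (adjusted p = 1.93e-05, but adjusted p = 0.389 with an estimated correlation). ZBTB16 (log2 difference -0.81, SE 0.74, adjusted p = 0.766), TBX21 (log2 difference -0.40, SE 0.40, adjusted p = 0.796) and EOMES (log2 difference -0.30, SE 0.37, adjusted p = 0.847) did not pass the test.

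limma called 368 genes, 223 higher and 145 lower in CD56+ T cells, 349 of them at least 2-fold, and 1351 (643 higher, 708 lower) with the replicate block. The block with the ratio gave 1377, and the ratio was higher by 0.34 on the log2 scale in CD56+ T cells (exact permutation p = 0.548, 4 of 5 pairs). NK cells lay above their array median on 1 of 5 arrays for SLAMF1 and CD28, on 2 for LAG3 and on 3 for LTK. RBM24 went from a log2 difference of 5.27 to 4.63 without CD56+ T replicate 1. CHST2 went from -3.87 to -4.48 and IGFBP7 from -4.20 to -4.85 without CD56+ T replicate 3. AQP3 went from 4.68 to 5.37, CCL20 from 4.10 to 4.86, LTK from 3.90 to 4.68, ME1 from 5.13 to 5.86 and RBM24 from 5.27 to 6.10 without CD56+ T replicate 5. LAG3 went from 3.73 to 4.37 without NK replicate 5. Leaving out 1 of 10 arrays ended calls (number of arrays) of KIR2DL1 (8), KIR2DL2 (5), KIR2DL3 (7) and NCAM1 (3) (highest adjusted p = 0.191).

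KIR+ and KIR- CD56+ T cells are the fractions set apart by KIR staining (n = 5 each). ME1 was at least 23.2-fold (adjusted p = 9.54e-05) lower in KIR+ cells, CCR6 at least 7.12-fold (adjusted p = 0.0125), the hypoxia-responsive factor EPAS1 8.81-fold (95% interval 4.05 to 19.2) and the granzyme gene GZMK 5.39-fold (95% interval 2.92 to 9.97). CCL20 was at least 4.87-fold (adjusted p = 0.0214) lower, NR4A3 8.002-fold (95% interval 3.62 to 17.7) and DPP4 6.52-fold (95% interval 2.998 to 14.2). The KIR genes used in the sort had higher estimates in KIR+ cells but did not pass the test: KIR2DL1 (log2 difference 3.09, SE 0.79, adjusted p = 0.114), KIR2DL2 (log2 difference 2.91, SE 0.73, adjusted p = 0.103), KIR2DL3 (log2 difference 2.25, SE 0.62, adjusted p = 0.174) and KIR3DL1 (log2 difference 2.08, SE 0.53, adjusted p = 0.114).

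Lower in KIR+ cells were also LTK at least 9.15-fold (adjusted p = 0.0125), IL4I1 at least 4.18-fold (adjusted p = 0.0197), RUNX2 5.95-fold (log2 -2.57, SE 0.50), ZNF165 at least 2.49-fold (adjusted p = 0.0286) and MCAM at least 4.69-fold (adjusted p = 0.0496). For RUNX2, 1 of 3 other probe sets pointed the other way. The 1 gene called higher in KIR+ cells without the block was RHOBTB3, by 4.47-fold (log2 2.16, SE 0.40, adjusted p = 0.0125), named here after its values were seen. With the replicate block KIR2DL1 (adjusted p = 0.000965), KIR2DL2 (0.00352), KIR2DL3 (0.00188) and KIR3DL1 (0.00364) were called higher, as was CD14 (adjusted p = 0.0349, against log2 difference 2.03, SE 0.87, adjusted p = 0.573 without the block). CD3D (log2 difference -0.16, SE 0.36, adjusted p = 0.978), CD3E (log2 difference -0.48, SE 0.54, adjusted p = 0.933), CD3G (log2 difference -0.01, SE 0.39, adjusted p = 0.998), NCAM1 (log2 difference 0.48, SE 0.37, adjusted p = 0.878), ZBTB16 (log2 difference -1.52, SE 0.74, adjusted p = 0.665), TBX21 (log2 difference 0.38, SE 0.40, adjusted p = 0.924) and EOMES (log2 difference 0.42, SE 0.37, adjusted p = 0.903) passed in neither fit.

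Innate-like T cell genes were lower in 4 of 17 over all genes, 14 adjusted over the list alone and 13 with the replicate block (camera adjusted p = 5.53e-24, and 0.00564 with an estimated correlation), with a median log2 difference of -1.52. In the same arrays the 3 prime to 5 prime ratio was higher in the KIR+ than in the KIR- array of all 5 pairs, by 0.82 on the log2 scale in the mean (two-sided exact permutation test, p = 0.183, and 0.0625 with paired sign changes, the smallest they can give). With the replicate block and this ratio as a covariate, chosen after the data were seen, 1 innate-like gene was called (median log2 difference -1.18, median SE 0.49, against -1.52 and 0.41 with the block alone). The list test kept its call (adjusted p = 2.29e-17, and p = 0.000544, not adjusted, with an estimated correlation), with 13 of 17 genes at an unadjusted p under 0.05. This fit called 2 KIR genes, while their median went from 2.04 (median SE 0.48) to 1.83 (SE 0.59). Lost calls (adjusted p = 0.0544 to 0.154) were those of CCR6 (-3.21, SE 0.54, to -2.59, SE 0.62), CCL20 (-3.93, SE 0.61, to -3.31, SE 0.72) and LTK (-4.002, SE 0.65, to -2.99, SE 0.70). DPP4 (-2.71, SE 0.42, to -2.24, SE 0.49), NR4A3 (-3.0003, SE 0.50, to -2.18, SE 0.53) and MCAM (-2.51, SE 0.46, to -1.85, SE 0.51) lost theirs too. For these 6 genes the differences were smaller and the SEs wider with the ratio. The KIR family had 0 of 13 called by limma over all genes (9 at an unadjusted p under 0.05), 9 higher adjusted over the list alone and 8 with the replicate block (adjusted p = 1.68e-12, but adjusted p = 0.132 with an estimated correlation). Monocyte markers had 0 of 17 called by limma (1 at an unadjusted p under 0.05) and 1 higher with the replicate block, with a median log2 difference of 0.76 (adjusted p = 0.000979, but adjusted p = 0.531 with an estimated correlation).

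Cytokines and chemokines had 1 of 18 lower over all genes and 3 adjusted over the list alone, and 2 higher and 3 lower with the replicate block (adjusted p = 0.0428, but adjusted p = 0.472 with an estimated correlation and 0.0810 with the replicate block). Homing receptors had 1 of 25 lower over all genes, 2 higher and 5 lower adjusted over the list alone, and 2 and 6 with the replicate block (median log2 difference 0.007, but mean -0.28 and test on the lower side). Immediate early and heat shock genes had 1 of 20 lower on both counts and 3 with the replicate block (adjusted p = 0.000319, but adjusted p = 0.472 with an estimated correlation). Cytotoxic effectors had only GZMK lower of 16 on both counts. limma called 0 of 24 cytokine receptor genes (8 at an unadjusted p under 0.05), 2 lower adjusted over the list alone and 7 lower with the replicate block (adjusted p = 0.000749, but adjusted p = 0.137 with an estimated correlation). It called 0 of 24 transcription factors (8 at an unadjusted p under 0.05) and 0 adjusted over the list alone, against 6 lower with the replicate block (camera adjusted p = 0.0420, but adjusted p = 0.309 with an estimated correlation). For T lineage genes it called 0 of 17 (4 at an unadjusted p under 0.05; camera adjusted p = 0.00111, but adjusted p = 0.217 with an estimated correlation). With the block and the ratio, limma called 0 cytokine receptors (9 at an unadjusted p under 0.05; median log2 difference -0.37, median SE 0.24, to -0.32, SE 0.29), 0 transcription factors (8; -0.19, SE 0.25, to -0.16, SE 0.29) and 0 immediate early genes (4; -0.57, SE 0.27, to -0.36, SE 0.30). It also called 0 homing receptors (9; 0.007, SE 0.39, to -0.09, SE 0.47), 0 cytokines (5; -0.18, SE 0.41, to -0.23, SE 0.50) and 0 monocyte markers (4; 0.76, SE 0.50, to 0.74, SE 0.61). The list tests of transcription factors (adjusted p = 0.0913) and of cytokines (0.158) then lost their calls.

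Without the replicate block, limma called 25 genes, 1 higher and 24 lower in the KIR+ fraction, all at least 2-fold. With it, limma called 401 (162 higher, 239 lower), and with the block and the ratio 28 (10 higher, 18 lower). Leaving out single arrays changed the count to 5 (without KIR- replicate 1, 2 of them higher), 4 (KIR- 3), 7 (KIR- 4), 60 (KIR- 5), 15 (KIR+ 1) and 9 (KIR+ 5, 4 of them higher), and the fit of only these 10 arrays called 4. KIR+ cells lay above their array median on 1 of 5 arrays for ME1 and on 2 for CCR6, LTK and MCAM. CCL20 went from a log2 difference of -3.93 to -4.79, IL4I1 from -3.52 to -4.20 and LTK from -4.002 to -4.63 without KIR- replicate 5. LTK went from -4.002 to -4.68 and ME1 from -5.52 to -6.24 without KIR+ replicate 4. Single arrays left out (number of 10) ended the calls of CCL20 (6), CCR6 (3), DPP4 (7), EPAS1 (1), GZMK (1), IL4I1 (6), LTK (5), MCAM (8), NR4A3 (4), RUNX2 (5) and ZNF165 (7) (highest adjusted p = 0.181). KIR2DL2 and KIR3DL1 were called in 1 of those 10 fits each.

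**Figure D2:**
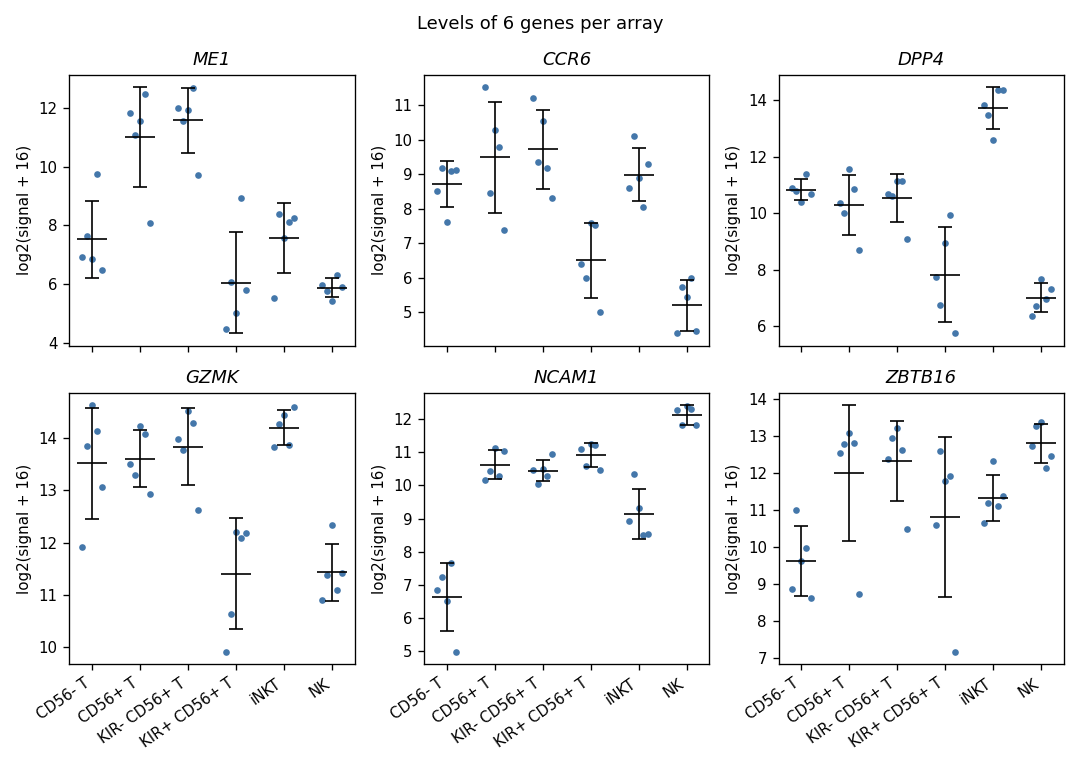
Levels of ME1, CCR6, DPP4, GZMK, NCAM1 and ZBTB16 on each array (y axis, log2 of signal + 16; x axis, the 6 groups; points are arrays). ME1 was at least 23.2-fold lower in the KIR+ than in the KIR- fraction, and NCAM1 was at least 12.2-fold higher in CD56+ than in CD56- T cells.

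KIR+ CD56+ T cells were set against NK cells (n = 5 each). CD3D was 24.99-fold (95% interval 15.1 to 41.4) higher in the T cells, CD8B 23.7-fold (95% interval 10.05 to 55.8) and THEMIS at least 6.47-fold (adjusted p = 3.94e-05). SH2D1B was 9.65-fold (95% interval 3.07 to 30.3) lower, ATP8B4 at least 6.52-fold (adjusted p = 9.75e-07) and CD38 7.41-fold (95% interval 2.77 to 19.9). KIR genes of the sort had lower estimates in the T cells and did not pass the test, among them KIR2DL1 (log2 difference -1.27, SE 0.79, adjusted p = 0.718) and KIR3DL1 (log2 difference -1.23, SE 0.53, adjusted p = 0.463).

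The checkpoint receptor CTLA4 was at least 5.71-fold (adjusted p = 0.000228) higher in KIR+ cells, UBASH3A at least 7.22-fold (adjusted p = 3.27e-08), MAL 17.7-fold (log2 4.15, SE 0.73), SYNM at least 12.4-fold (adjusted p = 0.000132) and TRAT1, an adaptor of the T cell receptor, at least 7.26-fold (adjusted p = 3.33e-07). LDB2 was at least 6.15-fold (adjusted p = 0.00115) lower, LINGO2 7.11-fold (log2 -2.83, SE 0.42), TNFRSF11A at least 5.84-fold (adjusted p = 0.00285), CHST2 6.76-fold (log2 -2.76, SE 0.63) and ZMAT4 at least 4.17-fold (adjusted p = 0.00684). NCAM1 (log2 difference -1.20, SE 0.37, adjusted p = 0.154) and ZBTB16 (log2 difference -1.99, SE 0.74, adjusted p = 0.304) were called lower only with the replicate block (adjusted p = 0.0283 and 0.0121).

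T lineage genes were higher in 13 of 17 over all genes and 16 adjusted over the list alone (camera adjusted p = 8.50e-53, and 4.03e-07 with an estimated correlation), with CD3G 11.5-fold and CD3E 4.39-fold. Naive and central memory genes were higher in 6 of 16 over all genes and 9 adjusted over the list alone (adjusted p = 1.51e-13, but adjusted p = 0.0680 with an estimated correlation). IL7R was 6.15-fold higher and NELL2 6.22-fold. NK receptors and adaptors were lower in 2 of 17 over all genes, 4 adjusted over the list alone and 7 with the replicate block (adjusted p = 1.84e-07, but adjusted p = 0.0618 with an estimated correlation), with FCER1G 5.39-fold lower. Cytokine receptors had 1 of 24 higher and 3 lower over all genes, and 2 and 3 adjusted over the list alone, with IL12RB2 at least 3.16-fold and IL18R1 2.89-fold lower. Antigen receptor signalling genes were lower in 3 of 17 over all genes, with 2 higher and 6 lower adjusted over the list alone and 2 and 5 with the replicate block (adjusted p = 0.0215, but adjusted p = 0.250 with an estimated correlation), SYK by 4.92-fold and LYN by 2.54-fold. Inhibitory receptors had 2 of 15 higher and 1 lower over all genes, 2 and 2 adjusted over the list alone, and 3 and 4 with the replicate block, with LAG3 at least 7.58-fold higher. limma called 0 of 13 KIR genes (2 at an unadjusted p under 0.05), 1 lower adjusted over the list alone and 2 lower with the replicate block (adjusted p = 2.31e-06, but adjusted p = 0.383 with an estimated correlation). It also called 0 of 16 cytotoxic effectors, with 0 at an unadjusted p under 0.05.

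limma called 136 genes, 90 higher and 46 lower in KIR+ cells, 133 of them at least 2-fold, and 668 (347 higher, 321 lower) with the replicate block. The ratio of 3 prime to 5 prime signal was higher in KIR+ cells in all 5 pairs, by 0.88 on the log2 scale in the mean (exact permutation p = 0.198, paired p = 0.0625, the smallest possible). With the block and this ratio, 166 genes were called higher and 86 lower. T lineage calls went from 15 to 13 (median log2 difference 3.14, median SE 0.36, to 3.58, SE 0.41) and NK receptors from 7 to 5 (-1.04, SE 0.38, to -1.11, SE 0.45). Antigen receptor signalling went from 7 to 3 (-0.32, SE 0.22, to -0.52, SE 0.26), and inhibitory receptors from 7 to 4 (0.12, SE 0.37, to -0.11, SE 0.46). The count was 88 without KIR+ replicate 1, and 86, 81 and 85 without NK replicates 2, 3 and 4. It was 71 in the fit of only these 10 arrays. For lower bounds, the lower group lay above its array median on 1 of 5 arrays for THEMIS and ATP8B4, on 2 for LDB2, ZMAT4 and LAG3 and on 3 for TNFRSF11A and IL12RB2. SYNM went from a log2 difference of 3.97 to 4.68 without KIR+ replicate 3. CTLA4 went from 4.29 to 4.88 without KIR+ replicate 5. LAG3 went from 3.63 to 4.27 without NK replicate 5. Without 1 array the call ended (number of 10 arrays) for CD38 (7), CD3E (9), CHST2 (5), FCER1G (5), IL12RB2 (2), IL18R1 (5), IL7R (6), LYN (7), NELL2 (7), SH2D1B (8) and SYK (7) (highest adjusted p = 0.166).

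iNKT cells were compared with CD56- T cells (n = 5 each). iNKT arrays do not pair and had the lowest monocyte markers, so iNKT calls may not reflect cell type alone. The spindle gene ASPM was at least 27.5-fold (adjusted p = 2.12e-10) higher in iNKT cells, STX3 98.1-fold (95% interval 58.003 to 166) and CSF2RB 56.6-fold (95% interval 24.2 to 132). The chemokine receptors CCR2 51.9-fold (95% interval 22.3 to 121) and CXCR6 40.8-fold (95% interval 21.6 to 77.4) were higher, whereas CCR7 was at least 114-fold (adjusted p = 4.57e-13) lower. CD8B was 108-fold (95% interval 45.7 to 254) lower and LEF1 100.0-fold (95% interval 42.6 to 235).

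Also higher were EGFL6 at least 27.04-fold (adjusted p = 2.63e-11), TMEM98 at least 17.2-fold (adjusted p = 4.18e-12), the costimulatory ligand TNFSF14 at least 23.7-fold (adjusted p = 7.10e-07) and the class II gene HLA-DQA1 62.2-fold (log2 5.96, SE 1.19). MMP25 was 71.4-fold (log2 6.16, SE 0.39) higher, although its other probe set pointed the other way. Also lower were TCEA3 at least 38.8-fold (adjusted p = 9.85e-10), AK5 at least 41.4-fold (adjusted p = 1.84e-10) and BEX2 84.4-fold (log2 -6.40, SE 0.34). Lysozyme (LYZ) was at least 96.9-fold (adjusted p = 5.57e-11) lower. The hemoglobin chain HBB was at least 71.1-fold (adjusted p = 6.21e-05) lower, with 1 of its 3 other probe sets pointing the other way. CD3D (log2 difference -0.04, SE 0.36, adjusted p = 0.945), CD3E (log2 difference -0.85, SE 0.54, adjusted p = 0.217), CD3G (log2 difference -0.40, SE 0.39, adjusted p = 0.437) and ZBTB16 (log2 difference 1.71, SE 0.74, adjusted p = 0.0675) did not pass the test. NCAM1 was at least 4.35-fold higher, with 2 of its 3 other probe sets pointing the other way, TBX21 2.95-fold and EOMES 4.09-fold.

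Proliferation genes were higher in 20 of 20, over all genes and adjusted over the list alone, with a median log2 difference of 4.12 (camera adjusted p = 2.97e-17, but adjusted p = 0.0668 with an estimated correlation). TOP2A, which untangles replicated DNA, was 32.4-fold higher and TYMS 26.3-fold. Cytokines and chemokines were higher in 11 of 18 on both counts (adjusted p = 0.000160, but adjusted p = 0.138 with an estimated correlation), with CCL4 17.4-fold and IL32 10.2-fold. Cytotoxic effectors had 10 of 16 higher and 2 lower over all genes, and 10 and 3 adjusted over the list alone (adjusted p = 0.000123, but adjusted p = 0.326 with an estimated correlation), with GZMB 13.6-fold and TNFSF10 13.4-fold higher. Naive and central memory genes had 1 of 16 higher and 11 lower on both counts (adjusted p = 1.72e-05, but adjusted p = 0.326 with an estimated correlation). Innate-like T cell genes had 9 of 17 higher and 2 lower over all genes, and 10 and 2 adjusted over the list alone (adjusted p = 0.00681, but adjusted p = 0.495 with an estimated correlation). DPP4 was 7.45-fold higher, and RORA was 5.45-fold lower, with 1 of its 6 other probe sets pointing the other way. Cytokine receptors had 11 of 24 higher and 6 lower over all genes, and 13 and 6 adjusted over the list alone, with the interleukin-2 receptor chain IL2RA 9.05-fold higher. limma called 0 of 13 KIR genes, with 0 at an unadjusted p under 0.05.

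Monocyte markers were lower in 15 of 17 over all genes and 16 adjusted over the list alone (adjusted p = 7.56e-07, but adjusted p = 0.383 with an estimated correlation), with S100A8 at least 23.3-fold and CD14 at least 4.03-fold. Platelet markers had 1 of 11 higher and 8 lower over all genes, and 1 and 9 adjusted over the list alone (adjusted p = 0.00633, but adjusted p = 0.516 with an estimated correlation), with PPBP at least 13.7-fold lower. B cell markers were lower in 7 of 13 on both counts (adjusted p = 0.0321, but adjusted p = 0.423 with an estimated correlation), with IGHM at least 8.84-fold. Of the 2 gamma delta receptor genes 1 was lower on both counts, TRDV3 by at least 10.03-fold. Erythroid markers were lower in 3 of 5, and granulocyte markers in 4 of 7, on both counts. Dendritic cell markers went both ways, with 2 of 8 higher and 3 lower over all genes, and 2 and 4 adjusted over the list alone (adjusted p = 0.969). Their median log2 difference was -1.07, while the test was on the higher side (mean -0.01), and GZMB is 1 of those higher.

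limma called 5351 genes, 2493 higher and 2858 lower in iNKT cells, 4428 of them at least 2-fold. The share of calls that were higher was 46.6%, and 62.0% after median centring of the arrays, which moved the median difference of all genes from -0.17 to 0.07. iNKT arrays had a 3 prime to 5 prime ratio lower by 1.02 on the log2 scale (exact permutation p = 0.151), and 5056 genes were called with it as a covariate. The list test of B cell markers then lost its call (adjusted p = 0.0743). The lower group lay above its array median on 1 of 5 arrays for TNFSF14 and TRDV3, on 2 for LYZ and HBB and on 3 for NCAM1. CD14 went from a log2 difference of -3.12 to -4.05, GZMB from 3.77 to 2.99, HBB from -6.81 to -7.78, IL32 from 3.35 to 2.74 and S100A8 from -5.40 to -6.25 without CD56- T replicate 1. HBB went from -6.81 to -6.07 without CD56- T replicate 4. CD8B went from -6.75 to -7.48 without iNKT replicate 1. ASPM went from 6.79 to 7.41 and TOP2A from 5.02 to 5.79 without iNKT replicate 2. CD3E was called without iNKT replicate 1 (-1.36, adjusted p = 0.0374) and ZBTB16 without CD56- T replicate 2 (2.06, adjusted p = 0.0377).

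**Figure D3:**
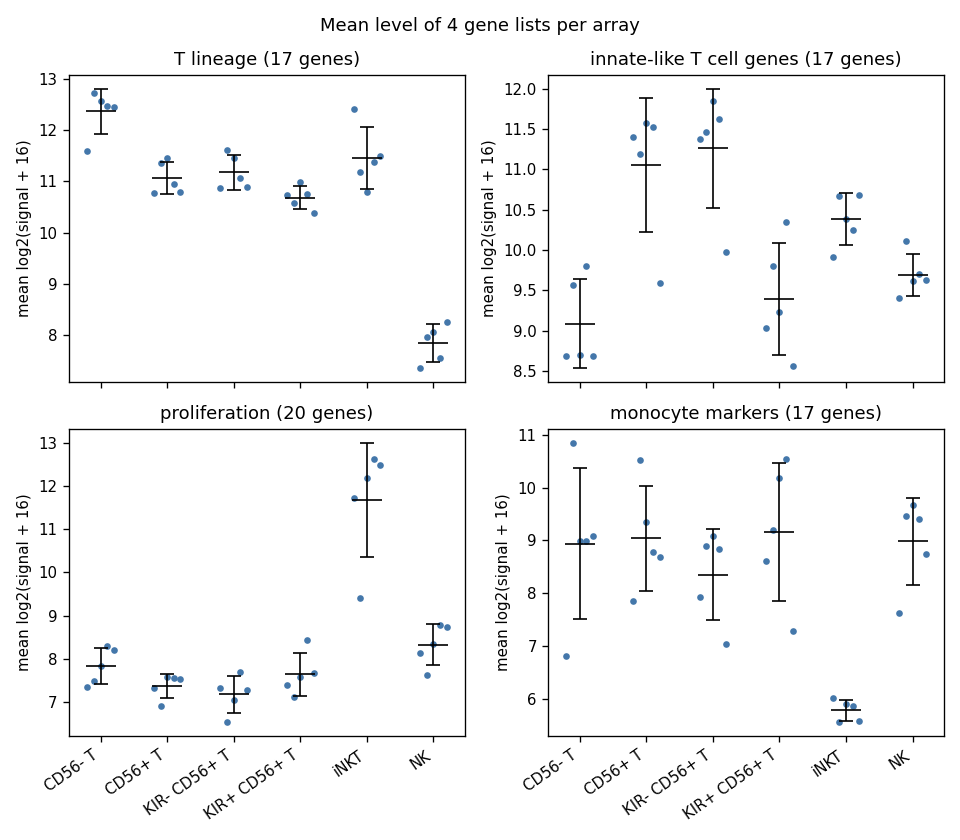
Mean level of the T lineage, innate-like T cell, proliferation and monocyte lists on each array (y axis, mean log2 of signal + 16; x axis, the 6 groups; points are arrays). The 5 iNKT arrays lie between 5.56 and 6.02 for monocyte markers, below all other arrays.

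iNKT cells were also compared with KIR- CD56+ T cells (n = 5 each). IL17RB, a receptor chain for interleukin-25, was at least 60.6-fold (adjusted p = 1.72e-09) higher in iNKT cells, CSF2RB at least 87.8-fold (adjusted p = 1.82e-10) and RRM2, a subunit of ribonucleotide reductase, 101-fold (95% interval 37.8 to 268). The T cell receptor delta segment TRDV3 was at least 64.96-fold (adjusted p = 2.91e-10) lower, and the kinase SIK1 90.8-fold (95% interval 37.5 to 219.9). NR4A2 was 83.1-fold (95% interval 32.97 to 209) lower and NR4A3 at least 27.4-fold (adjusted p = 4.34e-10).

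ASPM was at least 30.1-fold (adjusted p = 1.87e-10) higher, SMCO4 at least 69.1-fold (adjusted p = 1.14e-11), the serine synthesis enzyme PSAT1 at least 62.6-fold (adjusted p = 1.82e-11) and CEP55 at least 28.6-fold (adjusted p = 4.19e-10). MMP25 was 81.6-fold (log2 6.35, SE 0.39) higher, with its other probe set pointing the other way. LYZ was at least 101-fold (adjusted p = 3.90e-11) lower, HBB at least 50.3-fold (adjusted p = 0.000145), AGAP1 at least 48.999-fold (adjusted p = 3.96e-12) and BEX2 57.4-fold (log2 -5.84, SE 0.34). NCAM1 was 2.48-fold lower. CD3D (log2 difference 0.75, SE 0.36, adjusted p = 0.0924), CD14 (log2 difference -1.76, SE 0.87, adjusted p = 0.106), ZBTB16 (log2 difference -1.004, SE 0.74, adjusted p = 0.293), TBX21 (log2 difference -0.33, SE 0.40, adjusted p = 0.546) and EOMES (log2 difference 0.31, SE 0.37, adjusted p = 0.532) did not pass the test.

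Proliferation genes were higher in 20 of 20 on both counts, with a median log2 difference of 4.78 (camera adjusted p = 1.32e-17, but adjusted p = 0.0668 with an estimated correlation). Transcription factors were lower in 11 of 24 over all genes and 12 adjusted over the list alone (adjusted p = 0.000612, but adjusted p = 0.0683 with an estimated correlation), BCL6 by 19.8-fold and RORA by 12.9-fold. Innate-like T cell genes had 3 of 17 higher and 7 lower over all genes, and 3 and 8 adjusted over the list alone (adjusted p = 0.103), with CXCR6 14.3-fold higher and ME1 16.1-fold and LTK at least 13.6-fold lower. Immediate early and heat shock genes had 1 of 20 higher and 11 lower over all genes, and 1 and 13 adjusted over the list alone (adjusted p = 0.000206, but adjusted p = 0.472 with an estimated correlation). NK receptors and adaptors had 3 of 17 higher and 7 lower on both counts (adjusted p = 0.0686), with CD160 50.8-fold and KLRF1 37.2-fold lower. Regulatory T cell markers were higher in 4 of 8 over all genes and 5 adjusted over the list alone (adjusted p = 0.0360, but adjusted p = 0.245 with an estimated correlation), with IL2RA at least 14.3-fold. T lineage genes had 6 of 17 higher and 2 lower on both counts, with THEMIS 7.45-fold higher and CD8A 9.28-fold lower. Monocyte markers were lower in 12 of 17 over all genes and 13 adjusted over the list alone (adjusted p = 2.89e-05, but adjusted p = 0.472 with an estimated correlation). The 3 prime to 5 prime ratio was lower by 2.19 on the log2 scale on iNKT arrays (two-sided exact permutation test, p = 0.00794, the smallest that regrouping can give, adjusted p = 0.0556 over 7 comparisons).

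limma called 5720 genes, 2993 higher and 2727 lower, 4760 of them at least 2-fold. The share that was higher was 52.3%, and 67.3% after median centring, which moved the median difference of all genes from -0.07 to 0.20. With the ratio as a covariate it called 4319 (2452 higher, 1867 lower), and the list test of regulatory T cell markers lost its call (adjusted p = 0.0565). Of the 2 groups the lower lay above its array median on 1 of 5 arrays for TRDV3 and AGAP1, on 2 for PSAT1, LYZ and HBB and on 3 for CSF2RB, SMCO4, LTK and IL2RA. HBB went from a log2 difference of -6.31 to -7.21 without KIR- replicate 1, -5.71 without 4 and -5.73 without 5. LTK went from -4.01 to -4.63 without KIR- replicate 5. NR4A2 went from -6.38 to -5.56 without iNKT replicate 1. ASPM went from 6.82 to 7.44, CEP55 from 6.22 to 6.83, IL17RB from 7.21 to 6.59, PSAT1 from 6.28 to 7.03 and RRM2 from 6.65 to 7.50 without iNKT replicate 2. CD14 was called without KIR- replicate 1 (-2.31, adjusted p = 0.0410) and without KIR- replicate 5 (-2.34, adjusted p = 0.0357).

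Arrays were scored from 0 (CD56- T cells) to 1 (NK cells). CD56+ T cells lay at 0.652 ± 0.081 (SD, n = 5), the KIR- fraction at 0.614 ± 0.089, the KIR+ fraction at 0.762 ± 0.047 and iNKT cells at 0.507 ± 0.116. CD56- T cells themselves scored 0.073 ± 0.148 and NK cells 0.953 ± 0.128. The KIR+ fraction lay above the KIR- fraction in 5 of 5 pairs, by 0.148 in the mean (two-sided exact permutation test, p = 0.00794, the smallest that regrouping can give, adjusted p = 0.00952 over 6 tests). CD56+ T cells, both fractions and iNKT cells each lay above CD56- T cells with the same p. The KIR- fraction and iNKT cells differed by 0.107, which did not pass the exact permutation test (p = 0.159). Testing by replicate block, with 32 exact sign changes within pairs, gave an adjusted p of 0.075 for the KIR+ minus KIR- difference and for CD56+, KIR- and KIR+ cells against CD56- T cells, from the smallest p possible (0.0625). Without replicate 5, exact permutation gave adjusted p = 0.0571 for differences of CD56+ (0.532), KIR- (0.483) and KIR+ cells (0.630) from CD56- T cells. For iNKT cells (0.373) it gave 0.0857. The KIR+ minus KIR- difference was 0.155 without replicate 1 (adjusted p = 0.0686), 0.137 without 2 and 0.148 without 5 (0.103 for both, exact permutation). Fewer arrays raise the smallest possible p, so higher p need not mean weaker differences. Over alternatives the adjusted p ran from 0.00952 to 0.075 for the first 3 differences, to 0.0857 for iNKT cells and to 0.103 for KIR+ minus KIR-. The 3 prime to 5 prime ratio was also higher in NK than in CD56- T cells (by 1.10 on the log2 scale), in CD56+ than in CD56- T cells (1.44) and in KIR+ than in KIR- cells (0.82), in 5 of 5 pairs each. It was lower in iNKT than in CD56- T cells (by 1.02).

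**Figure D4:**
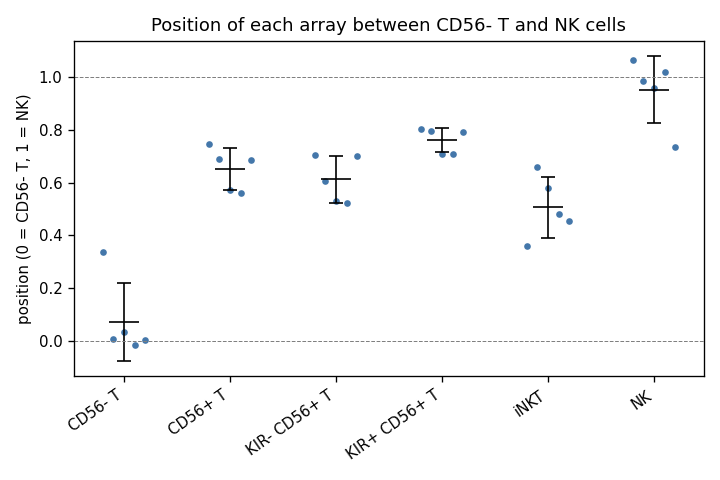
Position of each array between CD56- T cells (0) and NK cells (1) (y axis; x axis, the 6 groups; points are arrays, bars the mean and SD). The KIR+ fraction lies at 0.762 and the KIR- fraction at 0.614 in the mean.

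Across the 14327 genes, which are not independent replicates, the KIR+ minus KIR- difference correlated with the NK minus CD56- T difference (Pearson r = 0.291, Spearman rho = 0.237, two-sided exact permutation of the 10 KIR arrays, p = 0.00794, the smallest possible, adjusted p = 0.0159 over 2 tests). With the replicate block the adjusted p was 0.125, again from the smallest p that pair swaps can give (0.0625), and over the alternatives it ran from 0.0159 to 0.125. The correlation with the iNKT minus CD56- T difference was r = 0.0585 (rho = 0.0763, exact permutation p = 0.524). In the first correlation the 3 prime to 5 prime ratio differed in both comparisons too (by 0.82 and 1.10, in 5 of 5 pairs each).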

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

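The tests of culture, of dilution and of carried-over RNA were chosen only after the result was seen, and so were all fits with the 3 prime to 5 prime ratio and the SE set beside the innate-like median. In 12 of 198 groups of 5 values, 1 array stood so far from the other 4 that its gap exceeded 0.71 of the group's range, and chance gives about 1 in 20 groups. CD56- T replicate 1 stood apart in position (0.336), mean T lineage level (11.59), mean cytotoxic level (10.15), CD3D (13.69) and EOMES (9.18), all levels as log2. CD56+ T replicate 5 stood apart in innate-like genes (9.59) and ZBTB16 (8.74), and KIR- replicate 5 in innate-like genes (9.97). CD56+ T replicate 2 stood apart in transcription factors (12.16), and KIR+ replicate 4 in B cell markers (7.60). iNKT replicate 2 stood apart in proliferation genes (9.41) and iNKT replicate 3 in cytotoxic effectors (13.78).

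Proliferation genes were higher on iNKT arrays. With the 3 prime to 5 prime ratio as a covariate 20 of 20 stayed called against CD56- T cells (median log2 difference 4.11), which argues against weaker 3 prime bias as the whole cause. Culture or expansion of the iNKT cells before the sort could give such a difference (median log2 difference 4.12), but the labels name no culture step and no value here decides it. A difference in division between the cell types named by the design stays open, as untested.

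Innate-like genes were lower in KIR+ than in KIR- CD56+ T cells. Dilution by RNA of non-T cells would lower T lineage genes alike. These were lower too (mean -0.49, SD 0.34), but innate-like genes were lower by more in 5 of 5 pairs (mean difference -1.38, SD 0.75). That argues against dilution as the whole cause only. With the block and the ratio the median log2 difference went from -1.52 to -1.18 (jackknife SE 0.33 over replicate numbers). It passed the preset bound of -1, though not by that SE, and lay more than the SE below the -0.5 that 3 prime bias needs. The list test kept its call (adjusted p = 2.29e-17), and both values argue against 3 prime bias as the whole cause, but a part may come from it: 1 gene was called, with smaller differences for 15 and wider errors for 17 of 17. A difference between the KIR fractions themselves stays open, as untested.

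Monocyte markers varied together between arrays of 1 group (mean pairwise correlation 0.653, against at most 0.196 in 10000 random lists). It was 0.683 after the ratio was removed, which argues against 3 prime bias. RNA of monocytes carried into the sorted samples is a candidate explanation, as a hypothesis, although the sort stained CD14. LYZ had a mean signal of 14066 in KIR+ cells, 9530 in KIR- cells and 54.6 in iNKT cells, and S100A8 had 1591, 882 and 26.5. Of the 17 genes, written down beforehand, 2 (CLEC7A and FGL2) lay above the array median on all iNKT arrays and 0 are on another list, and no biological explanation was tested.

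Of 100 splits of the same 10 arrays per comparison, the real one included, only the real one called as many genes. Chance is unlikely for the 2 comparisons with iNKT cells, whose numbers do not pair. Real and highest other counts were 5351 and 1680 against CD56- T cells, and 5720 and 2410 against KIR- cells. Splits cannot assign this to cell type. In the other 5 comparisons the numbers pair the arrays, and most splits leave pairs together within a group. The real count and the highest other were 2652 and 2644 for NK cells against CD56- T cells (NK replicate 5 exchanged with CD56- T replicate 1), 2029 and 1785 for CD56+ against CD56- T cells (CD56+ T 3 with CD56- T 1), and 368 and 55 for CD56+ T against NK cells (NK 2 with CD56+ T 5). They were 25 and 24 for KIR+ against KIR- cells (KIR- 5 with KIR+ 2) and 136 and 6 for KIR+ against NK cells (NK 5 with KIR+ 5). Among the 11 to 13 other splits that part all pairs, as the real one does, the highest counts were 71, 303, 10, 0 and 6. With the replicate block, the 16 splits by swaps within pairs gave 4575 for the real one and at most 1342 for another, 4438 and 2200, 1351 and 78, 401 and 25, and 668 and 45. Both sets are too few for a share under 0.05.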

How the results depend on the processing

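The fits of 25 arrays with the replicate block, alone or with the 3 prime to 5 prime ratio, the ratio covariate for iNKT comparisons and the list tests under both are tests chosen only after the result was seen. The deposited signals carry no detection calls, so genes near background are limited to lower bounds of their fold, and 5 arrays per group limit what small differences can pass. The counts of calls ran over their alternatives from 1925 to 4575 for NK against CD56- T cells, 1379 to 4438 for CD56+ against CD56- T cells, 260 to 1377 for CD56+ T against NK cells, 4 to 401 for KIR+ against KIR- cells and 71 to 668 for KIR+ against NK cells. They ran from 4001 to 6412 for iNKT against CD56- T cells and from 4319 to 6749 for iNKT against KIR- cells, within 1.5 times under all 23 alternatives.

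With array weights CD56+ against CD56- T cells had 3324 calls and CD56+ T against NK cells 561. A pseudocount of 64 gave 38 calls for KIR+ against KIR- cells. With only the arrays of the 2 groups, which leaves fewer arrays to estimate the spread, there were 4 for KIR+ against KIR- and 71 for KIR+ against NK cells. For the others the cause was not tested. The replicate block gave 3354 calls for CD56+ against CD56- T cells, 804 for CD56+ T against NK cells, 123 for KIR+ against KIR- and 315 for KIR+ against NK cells with all 30 arrays. In 25 arrays it gave 4438, 1351, 401 and 668, and 4575 for NK against CD56- T cells. The block with the ratio gave 1377 for CD56+ T against NK cells and 2.5e+02 (166 higher and 86 lower) for KIR+ against NK cells. The block of 25 arrays kept all calls made without it, and changed the call of no named gene other than those given with it. In the list tests it ended 1 call, that of cytokines and chemokines in the KIR comparison (adjusted p = 0.0810), and added 10. Those were innate-like (0.0353), inhibitory (0.0313) and proliferation genes (0.0405) higher in NK than in CD56- T cells, and cytokines, inhibitory receptors (0.0123) and immediate early genes higher in CD56+ than in CD56- T cells. They were also NK receptors (0.0334) and inhibitory receptors (0.00389) higher and erythroid markers (0.0193) lower in KIR+ than in KIR- cells, and immediate early genes (0.00757) higher in KIR+ than in NK cells. iNKT numbers do not pair with the others; the 30-array block gave 6412 and 6749 calls there.

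Of the 62 list calls at the preset correlation, 6 held with an estimated correlation, 45 with fry, 59 after quantile normalization, 61 with the block and 54 with the ratio as a covariate (in the block without iNKT cells). The 8 calls lost with the ratio were transcription factors (adjusted p = 0.0913) and cytokines (0.158) in KIR+ against KIR- cells, and inhibitory receptors (0.0502) and B cell markers (0.0743) in iNKT against CD56- T cells. In iNKT against KIR- cells they were cytokines (0.0726), regulatory T cell (0.0565), platelet (0.235) and granulocyte markers (0.0965). It added 14: innate-like genes and inhibitory receptors in NK against CD56- T cells, cytokines, cytokine receptors, inhibitory receptors, platelet markers and immediate early genes in CD56+ against CD56- T cells, and NK and inhibitory receptors in KIR+ against KIR- cells. The others were cytotoxic effectors, cytokines and immediate early genes in KIR+ against NK cells, and KIR genes and NK receptors in iNKT against KIR- cells. The position of KIR+ cells was 0.710 on genes at least 4-fold different. Paired exact tests by replicate block gave position differences of 0.579 for CD56+, 0.541 for KIR- and 0.689 for KIR+ against CD56- T cells and 0.148 for KIR+ against KIR- cells, all with an adjusted p of 0.075, since 5 pairs allow no smaller p than 0.0625. For iNKT against CD56- T cells the same planned test gave 0.434 (0.075), which is void as a paired test, since those numbers do not pair. Without cross-hybridizing probe sets KIR+ minus KIR- was 0.141 (adjusted p = 0.0571). Over the alternatives these adjusted p ran from 0.00952 to 0.103. Leaving out 1 replicate number gave 0.530 to 0.626, 0.483 to 0.590, 0.630 to 0.745, 0.135 to 0.155 and 0.373 to 0.522. The KIR correlation with NK minus CD56- T was 0.291 with the replicate block (adjusted p = 0.125; 0.0159 to 0.125 over the alternatives).

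Leaving out 1 array gave 4 to 60 calls for KIR+ against KIR- cells (5 without KIR- 1, 15 without KIR+ 1, 4 without KIR- 3, 7 without KIR- 4, 60 without KIR- 5, 9 without KIR+ 5) and 81 to 119 for KIR+ against NK cells (88 without KIR+ 1, 86 without NK 2, 81 without NK 3, 85 without NK 4).

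Of 4790 values of named genes with 1 array left out, 4364 kept direction and side of the threshold, 380 lost the call, 11 gained it and 35 changed sign. Without cross-hybridizing probe sets, where another probe set stands for the gene, log2 differences changed sign for LAT2 (-0.16 in CD56+ against CD56- T, 0.0712 in CD56+ T against NK, -0.23 in NK against CD56- T, -0.88 in iNKT against CD56- T, -0.14 in iNKT against KIR-), MMP25 (-1.23 and -0.72 in the 2 iNKT comparisons), TRDV3 (-0.12 in CD56+ T and -0.41 in NK against CD56- T), LTB (-0.54), CD79B (-0.35), CD300A (-0.55) and HBB (0.0881). CD14 was -0.34 with array weights and -0.15 with the block and ratio in CD56+ against CD56- T cells, and 0.0202 with a pseudocount of 1 in NK against CD56- T cells. CD3D in iNKT against CD56- T cells was 0.50 after quantile normalization and 0.20 after median centring. In the KIR comparison the block with the ratio gave 0.12 for CD3D and 0.0395 for CD3G, and quantile normalization 0.0175 for CD3G. The block with the ratio gave 0.22 for TBX21 in KIR+ against NK cells, and the ratio -0.72 for CD3E in iNKT against KIR- cells. There KIR2DL2 was 0.17 with array weights, and KIR2DL3 was 0.23 after quantile normalization, 0.25 after median centring, 0.00209 with a pseudocount of 64 and 0.27 with array weights. The cause was not tested.

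With 1 array left out these ran from lowest to highest: CD14 -0.73 to 0.77 in CD56+ against CD56- T, -0.0389 to 0.81 in CD56+ T against NK and -1.12 to 0.37 in NK against CD56- T cells; CD3D -0.30 to 0.0588 in iNKT against CD56- T cells; CD3G -0.11 to 0.11 in the KIR comparison. In KIR+ against NK cells EOMES ran from -0.33 to 0.0381 and TBX21 from -0.39 to 0.12, and ZBTB16 in CD56+ T against NK cells from -1.08 to 0.00894. In iNKT against KIR- cells CD3E ran from -0.0670 to 0.99, CD3G from -0.0721 to 0.31, KIR2DL1 from -1.07 to 0.0507, KIR2DL2 from -0.91 to 0.14, KIR2DL3 from -0.36 to 0.22 and TBX21 from -0.54 to 0.0150. None of these passed the test with all arrays.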
